A study of Mus musculus with 10 samples.

How the data were processed

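RNA from mouse liver endothelial cells was sequenced on a BGISeq-500 instrument, with 5 libraries labelled Alk1-HEC-KO and 5 control libraries. Per the labels' protocols, cells other than hepatocytes were separated on a density gradient and endothelial cells were then captured with magnetic beads against CD146, the protein encoded by Mcam. Groups and replicate numbers came from the sample titles. The labels do not say that each library came from its own animal, so p-values measure the spread between these samples, which may be technical. Which exons of the targeted gene were deleted, the age of the mice and the library batches are not given in the sources used here.

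Reads were trimmed with Trim Galore 0.6.4 and quantified with kallisto 0.4.6 against GRCm38.p6, per the submitters' processing notes. The deposited files hold, for each library, expected counts (estimated counts per gene that need not be whole) and TPM values per gene. The step that summed transcripts to genes and the annotation release are not given in the sources used here. Each file listed 55385 genes, of which 55144 matched a symbol in GENCODE M21 by stable identifier and 54487 also by version. Coordinates are those of that annotation on GRCm38. Where several identifiers shared a symbol, the one with the most counts kept it. Kallisto shares reads between near-identical transcripts in proportion, so values of Mup, Cyp2c, Cyp2a, Ly6c, Hba, Hbb, Hspa1 and Serpina1 family members are uncertain, as are those of overlapping or antisense genes.

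Total estimated counts ran from 23489494 to 23602771 per library, so depth was nearly equal in both groups. Counting error is therefore small for abundant genes and large for genes with a few counts per library. No pair of libraries of a group agreed within sampling noise: the chi-square per degree of freedom over genes lay between 12.29 and 35.55, and all 10 libraries were kept as separate samples.

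The estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr with a minimum count of 10, which left 15043 genes holding 99.87 to 99.9% of the counts of each library. Libraries were scaled by TMM (factors 0.94 to 1.04) and genes were tested with the quasi-likelihood test (robust fit, genotype alone), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values come from this test unless another is named. Values in CPM were computed from the counts with TMM-scaled library sizes and are given as mean ± SD with n = 5 per group, and log2 CPM used a prior count of 2. For Acvrl1 an exact two-sided permutation test over the 252 assignments of the libraries was added.

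In all, 33 gene lists were tested with camera (limma 3.58.1) with a preset correlation of 0.01, with adjustment over the lists. Beside each result stand the members that passed over all genes and those that passed with p-values adjusted over the list alone. The same test was run with a correlation estimated per list. The list test compares a list with all other genes. Of the list members, 7 stood in more than 1 list. The gene lists, the tests, the alternatives except 1 and the rule for naming genes were fixed before the data were examined. That rule takes Acvrl1, the 12 genes with the largest rise and the 12 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between the groups (predicted genes, pseudogenes and antigen receptor segments left out), up to 4 called members per list or, where none was called, the 2 with the smallest p, a fixed set of vascular and cell type genes, and any of these with a library far from the others. Some genes that the rule takes are not reported here. Any other gene named was chosen after its values were seen.

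The procedure was tested on simulated counts for the same comparison, made from the control means, the real library sizes and the fitted dispersions. In them 200 genes with a control mean of at least 1 CPM were changed, and 14721 genes were tested. Of the changed genes, 68.7% were called at 1.5-fold, 82.1% at 2-fold and 97% at 4-fold. Of all calls 5.2% were false, and 1 gene was called where no change was simulated. Of 200 unchanged random lists 3.5% had an unadjusted camera p under 0.05, in simulated genes that vary independently of one another, which real genes do not.

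Alternatives were DESeq2 1.42.0, limma-voom, a fit without robust estimation, DESeq2 size factors, library size alone, no filter and a stricter filter on low counts, transcript length offsets, limma on log2 TPM with a pseudocount of 1 or 0.1, the replicate number as a block, a hepatocyte or macrophage covariate, each library left out, and other list tests. A fit without controls 4 and 5 was added after the data were examined.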

Results

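The series compared liver endothelial cells of mice with a targeted Acvrl1 gene with those of controls. Acvrl1 encodes ALK1, an endothelial receptor for BMP9 and BMP10. Gene expression was measured in 5 libraries labelled Alk1-HEC-KO and 5 control libraries, with totals of 23489494 to 23602771 estimated counts per library. Mitochondrially encoded transcripts made up 4.91% ± 0.87 (SD, n = 5) of the counts in controls and 3.89% ± 0.38 (SD, n = 5) in the libraries labelled Alk1-HEC-KO. Control 4 had the highest share, 6.43%.

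Acvrl1 itself was higher, not lower, in the libraries labelled Alk1-HEC-KO. Acvrl1 (ENSMUSG00000000530.16) lies on chromosome 15 from 101128522 to 101145336, on the plus strand (GRCm38). Its level was 124, 125, 136, 114 and 135 CPM in controls 1 to 5 and 239, 246, 250, 258 and 245 CPM in libraries 1 to 5 labelled Alk1-HEC-KO. The means were 127 ± 8.73 and 248 ± 6.94 CPM (SD, n = 5 each), a 1.95-fold difference (log2 fold change 0.96 ± 0.05 SE, edgeR adjusted p = 1.7e-07). In the deposited TPM the means were 74.8 ± 8.13 and 143 ± 2.9 (SD, n = 5 each). The exact two-sided permutation p was 0.0079, the smallest that 5 against 5 can give. Gene-level counts do not show which exons the reads came from, so transcript from a deleted allele may be counted. Because the targeted gene went against the label, the group is called the knockout-labelled libraries here, and every direction given is that of these libraries against the controls.

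**Figure D1:**
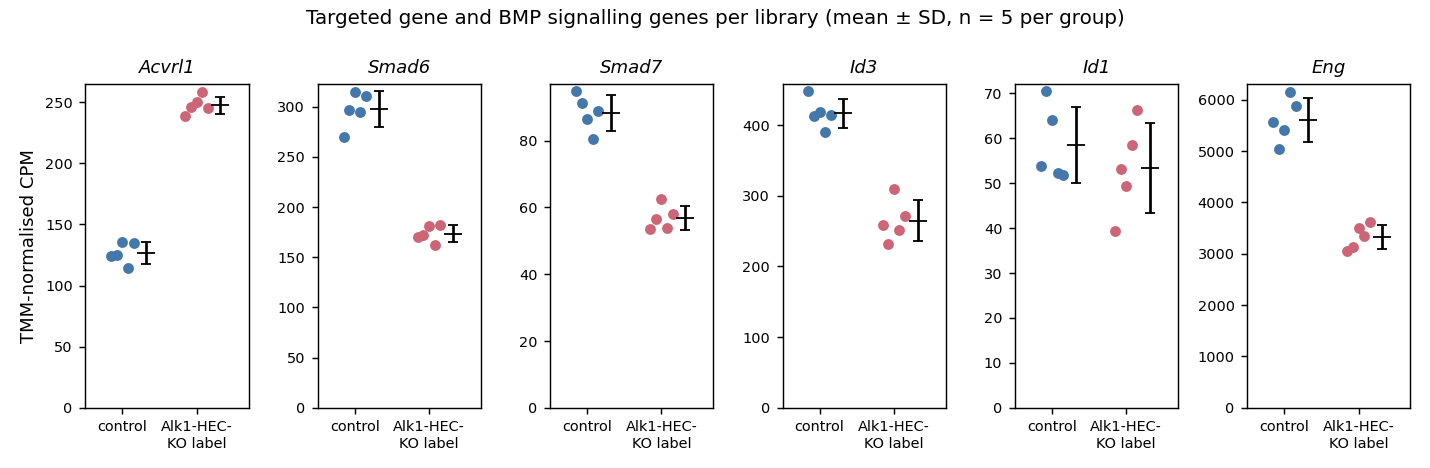
TMM-normalised CPM (y axes, from 0) of Acvrl1, Smad6, Smad7, Id3, Id1 and Eng in the 5 control and 5 knockout-labelled libraries (points), with the mean and SD as bars. Acvrl1 is at 114 to 136 CPM in controls and 239 to 258 CPM in knockout-labelled libraries, while Smad6, Smad7, Id3 and Eng are lower there without overlap.

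Several inhibitors and targets of BMP signalling were lower in the knockout-labelled libraries. Of the 12 ALK1-BMP target genes 7 fell, 2 rose and 3 did not pass (adjusted over the list alone, 7 fell and 3 rose). Smad6 and Smad7, inhibitory SMADs, fell by 0.78 ± 0.06 and by 0.64 ± 0.06 on the log2 scale (SE). Id3 fell by 0.65 ± 0.07 and Bambi, a decoy receptor, fell by 1.32 ± 0.2. Smad9 fell by 1.05 ± 0.26 from a low level of 1.58 CPM, and was not called with limma on log2(TPM + 1) (-0.24, adjusted p = 0.056) or without controls 4 and 5 (adjusted p = 0.091). Id1 was at 58.5 ± 8.41 CPM in controls and 53.3 ± 10 CPM in knockout-labelled libraries (SD, n = 5 each; edgeR adjusted p = 0.55). Stmn2 rose by 1.51 ± 0.22. Tmem100 was at 0.345 and 0.762 CPM, and its call (adjusted p = 0.047) ended without any of controls 1 to 4 or knockout-labelled libraries 2 to 5, with adjusted p from 0.069 to 0.12. The list was lower by camera (adjusted p = 1.1e-04), and not with an estimated correlation (adjusted p = 0.15).

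Receptors, ligands and SMADs of the BMP and TGF-beta families moved both ways. Of 23 members 5 rose, 7 fell and 11 did not pass (adjusted over the list alone, 7 rose and 7 fell), and the list did not pass (camera adjusted p = 0.52; adjusted p = 0.7 with an estimated correlation; median log2 fold change 0.04, mean -0.13). The ligands Bmp4 and Tgfb2 fell by 2.45 ± 0.18 and by 1.95 ± 0.16 on the log2 scale (SE), and Bmp6 fell by 0.66 ± 0.08. Eng, the co-receptor endoglin, fell from 5610 ± 430 to 3330 ± 240 CPM (SD, n = 5 each; edgeR adjusted p = 1.4e-05). Bmpr2 fell by 0.36 ± 0.08, and Smad1 rose by 0.93 ± 0.06.

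Genes of central vein endothelium fell the most of the vascular lists. Of 12 members 10 fell, 1 rose and 1 did not pass (adjusted over the list alone, 10 fell and 2 rose). Rspo3 (ENSMUSG00000019880.10), an enhancer of Wnt signalling on chromosome 10 from 29452416 to 29535867, fell from 241 ± 11.3 to 6.85 ± 1.99 CPM (SD, n = 5 each; 35.2-fold, edgeR adjusted p = 3.6e-08). Wnt9b (ENSMUSG00000018486.2), a Wnt ligand on chromosome 11 from 103727364 to 103749821, fell 13.6-fold (159 ± 38 to 11.6 ± 3.77 CPM, edgeR adjusted p = 9.0e-06), and Wnt2 fell 3.82-fold (361 ± 46.8 to 94.6 ± 30.9 CPM, edgeR adjusted p = 1.8e-04). Selp fell 10-fold and Cdh13 5.75-fold. The list was lower by camera (adjusted p = 1.5e-29; adjusted p = 0.0092 with an estimated correlation).

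Genes of sinusoidal endothelial identity were lower by smaller amounts. Of the 17 members of the LSEC identity list 15 fell and 2 did not pass (adjusted over the list alone, 16 fell). Gata4, a transcription factor of sinusoidal endothelium, fell 1.67-fold (481 ± 32.9 to 288 ± 20.2 CPM, SD, n = 5 each; edgeR adjusted p = 6.9e-06). F8, coagulation factor VIII, fell by 0.65 ± 0.07 on the log2 scale (SE), Clec4g fell by 0.63 ± 0.09 and Oit3 fell by 0.61 ± 0.08. The scavenger receptors Stab1 and Stab2 fell by 0.5 ± 0.05 and by 0.35 ± 0.08, Bmp2 fell by 0.39 ± 0.08 and Maf fell by 0.25 ± 0.06. Lyve1 was at 770 ± 148 and 648 ± 89.5 CPM (SD, n = 5 each; edgeR adjusted p = 0.24). The list was lower by camera (adjusted p = 1.2e-15; adjusted p = 0.021 with an estimated correlation).

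Genes of continuous, non-sinusoidal endothelium were mostly higher. Of 14 members 10 rose, 2 fell and 2 did not pass (adjusted over the list alone, 11 rose and 2 fell). Cd34, a sialomucin of capillary endothelium, rose 8.61-fold (64.1 ± 21.8 to 552 ± 43.2 CPM, SD, n = 5 each; edgeR adjusted p = 4.3e-06). Ly6c1 rose 29.9-fold and Cav1, the coat protein of caveolae, 4.45-fold. Vwf, von Willebrand factor, went the other way and fell 3.26-fold (463 ± 72.8 to 142 ± 33.2 CPM). The list was higher by camera (adjusted p = 2.2e-18; adjusted p = 8.6e-04 with an estimated correlation).

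Of 14 tip cell and sprouting genes 11 rose and 3 did not pass (adjusted over the list alone, 13 rose), and the list was higher by camera (adjusted p = 1.3e-18; adjusted p = 0.014 with an estimated correlation). Apln, the ligand apelin, rose 23.1-fold (6.22 ± 4.34 to 144 ± 30.4 CPM, SD, n = 5 each; edgeR adjusted p = 1.8e-04) and its receptor Aplnr 9.57-fold. Igfbp3 rose 22.1-fold. Pgf, placental growth factor, rose 65.6-fold, and 312-fold without control 5. Controls 1 to 4 held 9 counts of Pgf in total, so the size of that fold is uncertain. Esm1 was at 72 ± 43.6 and 200 ± 58.2 CPM without overlap between the groups (SD, n = 5 each; edgeR adjusted p = 0.072). It was called with DESeq2 (adjusted p = 0.019) and without robust estimation (0.032), within a range of 0.019 to 0.24 over 24 alternatives. Angpt2 was at 48.2 ± 11.5 and 42.3 ± 3.9 CPM (SD, n = 5 each; edgeR adjusted p = 0.45).

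**Figure D2:**
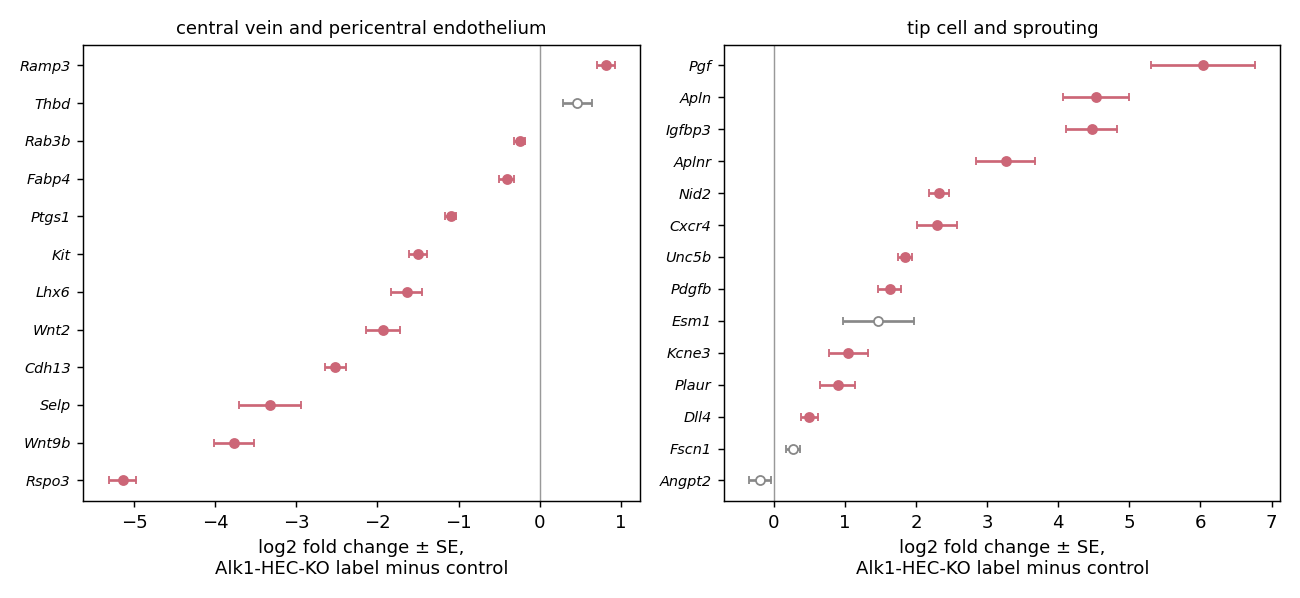
Log2 fold change, knockout-labelled libraries minus controls (x axes, bars are SE), of each member of the central vein and tip cell lists (y axes); filled red points passed the edgeR test, open grey points did not. Rspo3, at -5.14, and Pgf, at 6.04, mark the ends.

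Arterial and Notch genes rose in part. Of 15 arterial and portal genes 6 rose, 1 fell and 8 did not pass (adjusted over the list alone, 9 rose and 2 fell; camera adjusted p = 0.0063, adjusted p = 0.23 with an estimated correlation). Sema3g rose by 2.62 ± 0.28 on the log2 scale (SE), Efnb2 by 0.75 ± 0.12 and Gja5 by 0.74 ± 0.14, while Bmx fell by 0.68 ± 0.12. Gja4 was at 348 ± 198 and 194 ± 41.8 CPM (SD, n = 5 each; edgeR adjusted p = 0.11). Of 15 Notch pathway genes 4 rose, 1 fell and 10 did not pass (adjusted over the list alone, 6 rose and 1 fell; camera adjusted p = 0.0068, adjusted p = 0.18 with an estimated correlation). The ligand Jag2 rose 24.3-fold (1.91 ± 1 to 46.6 ± 5.31 CPM, SD, n = 5 each), and Dll4, Notch4 and Mfng rose by 0.5 ± 0.12, 0.55 ± 0.08 and 0.51 ± 0.08. Dll4 was not called with no filter (adjusted p = 0.051) or with the hepatocyte covariate (adjusted p = 0.13). Lfng, a glycosyltransferase that modifies Notch, fell by 1.07 ± 0.14.

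General endothelial genes moved by less than 2 times. Of 12 members of the pan-endothelial list 6 rose, 1 fell and 5 did not pass (adjusted over the list alone, 7 rose and 2 fell; camera adjusted p = 0.021, adjusted p = 0.24 with an estimated correlation). Mcam, whose protein is the target of the capture beads, rose 1.64-fold (330 ± 44.4 to 541 ± 35.8 CPM, SD, n = 5 each; edgeR adjusted p = 1.1e-04). Fli1 and Sox18 rose by 0.37 ± 0.07 and 0.33 ± 0.07 on the log2 scale (SE). The receptors Tek, Kdr and Flt1 fell by 0.34 ± 0.06, by 0.33 ± 0.07 and by 0.32 ± 0.05. In the VEGF and angiopoietin list 4 of 14 members rose, 3 fell and 7 did not pass (adjusted over the list alone, 5 rose and 6 fell; camera adjusted p = 0.8, adjusted p = 0.93 with an estimated correlation); its median was -0.17 and its mean 0.16. Angptl4 and Angpt1 rose by 2.19 ± 0.33 and 1.08 ± 0.19, and Vegfc by 0.49 ± 0.12. Of 7 lymphatic genes 2 rose and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.092, and 0.023 without knockout-labelled library 4; adjusted p = 0.51 with an estimated correlation). Flrt2 rose by 0.83 ± 0.11. Prox1 rose by 0.6 ± 0.17, a call that ended without control 2, 3 or 4 or knockout-labelled library 2 or 3 (adjusted p from 0.054 to 0.068).

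Of 18 vessel matrix genes 9 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 7.1e-06; adjusted p = 0.0092 with an estimated correlation). Col15a1, a basement membrane collagen, rose 50.9-fold (3 ± 2.99 to 153 ± 31.9 CPM, SD, n = 5 each; edgeR adjusted p = 7.6e-05), and 91.6-fold without control 5. Sparcl1 rose 4.61-fold, and Adamts1 and Col5a1 by 0.8 ± 0.13 and 0.71 ± 0.15 on the log2 scale (SE). Of 10 endothelial to mesenchymal transition genes 2 rose, 1 fell and 7 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.28; adjusted p = 0.54 with an estimated correlation). Snai2 and Vim rose by 0.9 ± 0.12 and 0.61 ± 0.06. Zeb2 fell by 0.39 ± 0.12, a call that ended without control 1, 3 or 5 or knockout-labelled library 2, 4 or 5 (adjusted p from 0.068 to 0.085).

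Wnt feedback and shear-responsive genes went both ways. Of 11 Wnt feedback genes 2 rose, 3 fell and 6 did not pass (adjusted over the list alone, 2 rose and 4 fell). The list was lower by camera (adjusted p = 0.028), not without knockout-labelled library 3 (adjusted p = 0.077) nor with an estimated correlation (adjusted p = 0.23). Dkk3 and Rnf43 fell by 2.13 ± 0.17 and by 1.45 ± 0.24 on the log2 scale (SE), and Dkk2 and Apcdd1 rose by 1.85 ± 0.31 and 0.78 ± 0.17. Rnf43 was not called with transcript length offsets (adjusted p = 0.1) or with limma on log2 TPM (0.14 and 0.1 with pseudocounts of 1 and 0.1), and its log2 fold change was -0.49 with the pseudocount of 1, where that of Dkk2 was 0.56. Of 11 shear-responsive genes 6 rose, 4 fell and 1 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.2; adjusted p = 0.44 with an estimated correlation). Nos3, endothelial nitric oxide synthase, and Pi16 rose by 0.56 ± 0.1 and 1.12 ± 0.27, and Edn1, endothelin 1, fell by 0.96 ± 0.23. Pi16 was not called with no filter (adjusted p = 0.064), the replicate block (0.066), the hepatocyte covariate (0.07) or without controls 4 and 5 (0.12). Nor was Edn1 with no filter (0.05), the hepatocyte covariate (0.073) or limma on log2 TPM (0.054 and 0.057 with pseudocounts of 1 and 0.1). Klf2 was at 509 ± 106 and 495 ± 117 CPM (SD, n = 5 each; edgeR adjusted p = 0.92). Klf4 was at 88.3 ± 13.5 and 135 ± 34.1 CPM (edgeR adjusted p = 0.038), a call that ended without control 1, 2, 3 or 5 or knockout-labelled library 3, 4 or 5 (adjusted p from 0.062 to 0.083).

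Among general processes, most interferon response genes rose: of 15 members 10 rose and 5 did not pass (adjusted over the list alone, 12 rose; camera adjusted p = 2.3e-06, adjusted p = 0.15 with an estimated correlation). Rsad2 rose by 1.68 ± 0.13 on the log2 scale (SE), and Ifit1, Irf7 and Ifit2 by 0.7 ± 0.1, 0.55 ± 0.12 and 0.54 ± 0.09. Of 15 cholesterol synthesis genes 2 fell, with the same count adjusted over the list alone, and Sc5d among them fell by 0.49 ± 0.09. That list was lower by camera (adjusted p = 0.023), not without control 5 (adjusted p = 0.079) or knockout-labelled library 4 (adjusted p = 0.061), nor with an estimated correlation (adjusted p = 0.51). Of 21 cell cycle genes 1 rose, Ccnd1, and 1 fell, Mcm3, with the same counts adjusted over the list alone (camera adjusted p = 0.088; 0.0095 without control 5, and 0.024 and 0.019 without knockout-labelled library 1 or 2; adjusted p = 0.77 with an estimated correlation). Mki67, a proliferation marker, was at 15.2 ± 5.06 and 21.7 ± 6.24 CPM (SD, n = 5 each; edgeR adjusted p = 0.21). Of 17 glycolysis and hypoxia genes Aldoa alone was called and fell by 0.33 ± 0.07 (1 fell adjusted over the list alone; camera adjusted p = 0.62, adjusted p = 0.88 with an estimated correlation). Of 14 adhesion and inflammation genes 1 rose, Icam2, by 0.35 ± 0.06 (1 rose adjusted over the list alone; camera adjusted p = 0.87, adjusted p = 0.98 with an estimated correlation).

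Markers of RNA quality were also read. Of 13 mitochondrially encoded mRNAs 6 fell and 7 did not pass (adjusted over the list alone, 11 fell; camera adjusted p = 4.3e-04, adjusted p = 0.51 with an estimated correlation). The log2 fold changes were -0.49 for mt-Nd2 and mt-Nd4, -0.47 for mt-Nd6 and -0.43 for mt-Cytb. With the hepatocyte covariate none of the 4 was called, with log2 fold changes of -0.38, -0.41, -0.29 and -0.30 (adjusted p = 0.21, 0.16, 0.29 and 0.29). Nor was any with no filter (adjusted p from 0.064 to 0.11). All 4 calls ended without knockout-labelled library 2 or 5 (adjusted p from 0.053 to 0.086). They also ended without knockout-labelled library 1 for mt-Nd2 (0.064), mt-Nd6 (0.07) and mt-Cytb (0.075), library 3 for mt-Cytb (0.052), library 4 for mt-Nd6 (0.063), control 3 for mt-Nd6 (0.073) and mt-Cytb (0.076), and control 4 for mt-Cytb (0.054). Of 14 dissociation and stress response genes 1 rose, Btg2, by 0.54 ± 0.13 on the log2 scale (1 rose adjusted over the list alone; camera adjusted p = 0.2, and 0.0042 without knockout-labelled library 2; adjusted p = 0.77 with an estimated correlation).

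Hepatocyte transcripts, from a cell type the gradient was used to remove, moved unequally. Of 17 members of the hepatocyte list 3 fell and 14 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0093; adjusted p = 0.65 with an estimated correlation). The drug-metabolising enzymes Cyp2e1 and Cyp3a11 fell 9.86-fold (146 ± 123 to 14.8 ± 3.95 CPM) and 8.55-fold (110 ± 83.8 to 12.8 ± 4.84 CPM, SD, n = 5 each). With the hepatocyte covariate, which is made from this list, their log2 fold changes were -1.67 and -1.65, against -3.3 and -3.1 without it. Apoa2 fell 4.42-fold (edgeR adjusted p = 0.037), a call that ended without control 2 or 4 or any of the knockout-labelled libraries (adjusted p from 0.062 to 0.085). Alb, serum albumin, was at 471 ± 194 and 447 ± 165 CPM (SD, n = 5 each; edgeR adjusted p = 0.91).

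Among genes listed for other cells, 3 collagens and 5 of 7 bile duct markers rose. Of 12 stellate cell and fibroblast genes 3 rose, 1 fell and 8 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 1.1e-04; adjusted p = 0.27 with an estimated correlation). Col1a1, Col1a2 and Col3a1, the only members that rose, did so 3.06-fold, 2.73-fold and 2.34-fold, and Ecm1 fell by 0.74 ± 0.13 on the log2 scale (SE). Which cells the collagen reads came from was not tested. Dcn, a fibroblast marker, was at 67.1 ± 24.8 and 76.2 ± 22.6 CPM (SD, n = 5 each; edgeR adjusted p = 0.7). Of 7 cholangiocyte genes 5 rose and 2 did not pass (adjusted over the list alone, 7 rose; camera adjusted p = 4.1e-05, adjusted p = 0.22 with an estimated correlation), among them Epcam, Spp1, Sox9 and Cldn7 by 1.14 ± 0.14, 1.12 ± 0.15, 1.09 ± 0.17 and 0.96 ± 0.19. Of 9 smooth muscle and pericyte genes 3 rose and 6 did not pass, with the same counts adjusted over the list alone. That list did not pass (camera adjusted p = 0.052; adjusted p = 0.51 with an estimated correlation) but did without control 1 (adjusted p = 0.015), 2 (0.022) or 5 (0.041), or knockout-labelled library 2 (0.023), 4 or 5 (0.049 each). The channel subunits Kcnj8 and Abcc9 rose by 1.95 ± 0.3 and 1.64 ± 0.31, and Rgs5 by 0.75 ± 0.19.

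Of 9 B and plasma cell genes 4 rose and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0043; adjusted p = 0.47 with an estimated correlation). Ebf1 and Ighm rose by 1.92 ± 0.24 and 1.11 ± 0.19 on the log2 scale (SE). Jchain rose by 1.49 ± 0.4, not called without control 4 or knockout-labelled library 2 or 4 (adjusted p from 0.052 to 0.06), and Mzb1 by 1.06 ± 0.3, not called without control 1, 2 or 3 or knockout-labelled library 2 or 4 (adjusted p from 0.054 to 0.07). Of 12 T and NK cell genes 3 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.36; adjusted p = 0.77 with an estimated correlation; median 0.03, mean -0.23). Cd3d fell by 1.06 ± 0.29, not called without control 1 (adjusted p = 0.05). Cd4 fell by 0.92 ± 0.26, not called without control 3 or 4 or knockout-labelled library 3 or 5 (adjusted p from 0.052 to 0.065). Trac fell by 1.2 ± 0.38, not called without control 1, 3, 4 or 5 or knockout-labelled library 2, 3 or 4 (adjusted p from 0.066 to 0.1).

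Myeloid and blood lists did not pass. No gene of 12 in the Kupffer cell and macrophage list passed, alone or over all genes (camera adjusted p = 1, adjusted p = 1 with an estimated correlation; median -0.06, mean 0.05). Clec4f, a Kupffer cell lectin, was at 213 ± 106 and 208 ± 78.9 CPM (edgeR adjusted p = 0.96), Marco at 20.3 ± 10.6 and 44.6 ± 20.3 CPM (adjusted p = 0.12) and C1qb at 188 ± 101 and 162 ± 55.3 CPM (adjusted p = 0.76; SD, n = 5 each). No gene of 10 in the neutrophil and monocyte list passed either way (camera adjusted p = 0.9, test direction down with a median of 0.23; adjusted p = 0.98 with an estimated correlation). Ly6c2 and Ccr2 had edgeR adjusted p of 0.26 and 0.29. Of 8 dendritic cell genes 1 rose, Clec9a, by 0.6 ± 0.1 (4 adjusted over the list alone; camera adjusted p = 0.1, and 0.047 without knockout-labelled library 5; adjusted p = 0.51 with an estimated correlation). No gene of 5 in the erythroid list passed either way (camera adjusted p = 0.63; adjusted p = 0.88 with an estimated correlation), with Hba-a2 and Hbb-bs at edgeR adjusted p of 0.48 and 0.5. Of 4 platelet genes 1 fell, Gp1ba, by 1.01 ± 0.14 (1 adjusted over the list alone; camera adjusted p = 0.43, adjusted p = 0.7 with an estimated correlation).

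**Figure D3:**
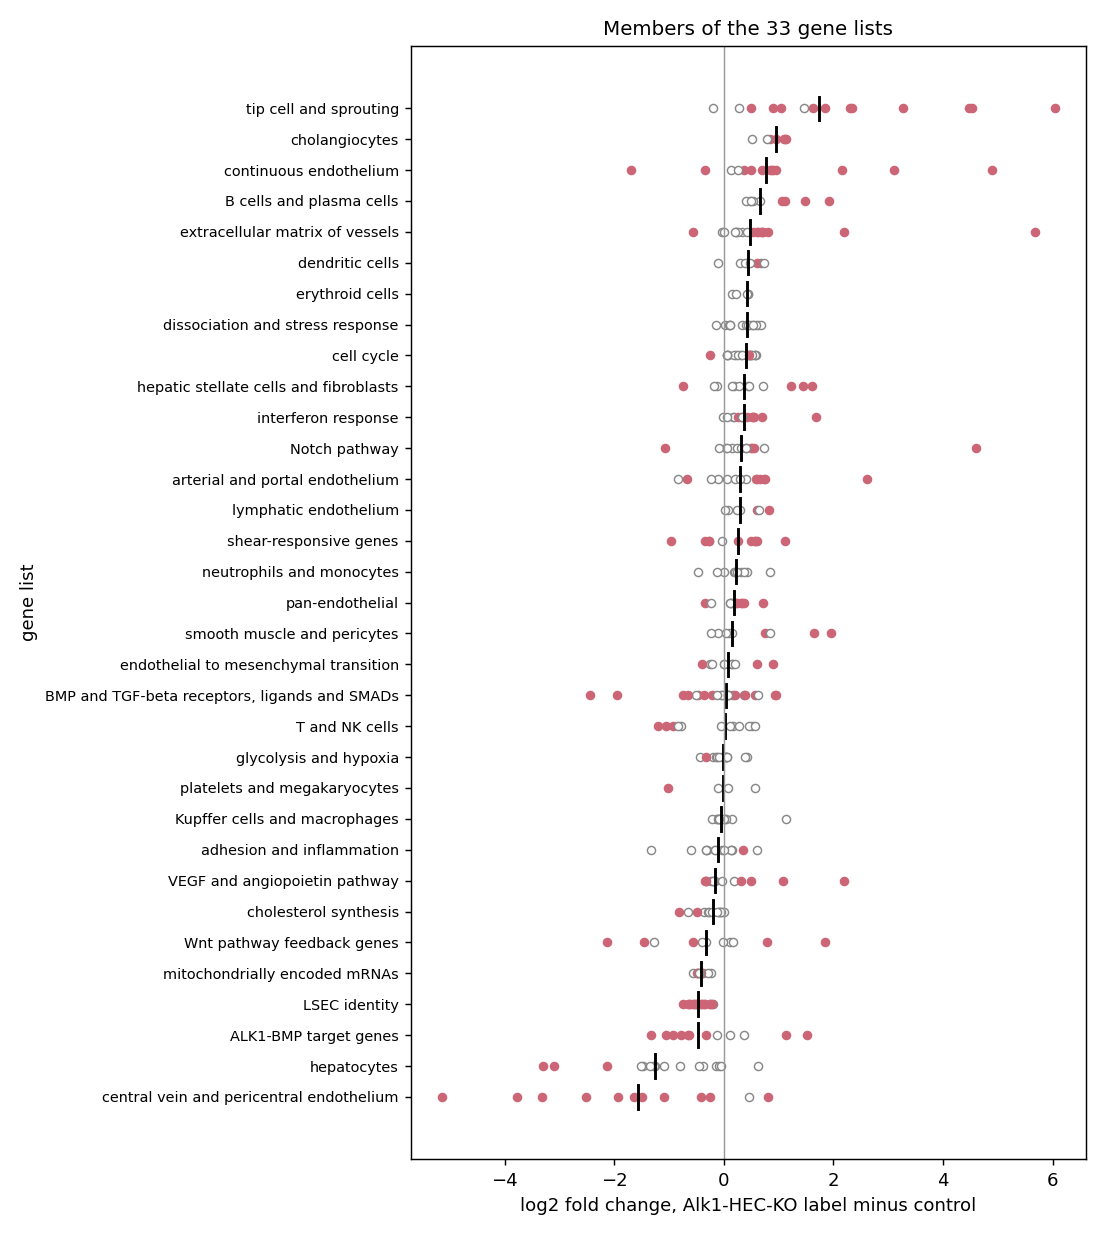
Log2 fold change, knockout-labelled libraries minus controls (x axis), of every tested member of the 33 gene lists (y axis, ordered by median). Filled red points passed the edgeR test over all genes, open grey points did not, and black bars are medians, from -1.57 for central vein genes to 1.74 for tip cell genes.

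Across all genes, the 12 with the largest rise by the rule for naming genes were Prnd, Col28a1, Pgf, Col15a1, Rgcc, Tmem178, Vwa1, Kcna5, Nos2, Ly6c1, Jag2 and Apln. Prnd (ENSMUSG00000027338.16), the gene of the prion-like protein doppel on chromosome 2 from 131950861 to 131956130, rose 98.4-fold (1.04 ± 2.07 to 103 ± 19.4 CPM, SD, n = 5 each; edgeR adjusted p = 6.5e-04). Rgcc rose 44.3-fold, Tmem178 38.9-fold and Kcna5 32.5-fold. Control 5 held several of these genes above the other controls, and without it the folds were 907 for Prnd, 595 for Col28a1 (88.9 with it), 52.1 for Vwa1 (33.2) and 50.2 for Nos2 (31.7). Controls 1 to 4 held 10 counts of Prnd and 6 of Col28a1 in total, so the sizes of their folds are uncertain. Over 24 alternatives the log2 fold change of Prnd ran from 5.79 to 9.93.

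The genes with the largest fall by that rule included, beside Rspo3 and Wnt9b, genes of hepatocytes: Mup17, Mup9, Mup15, Mup19, Mup16, Cyp2c37, Cyp2a5, Cyp1a2 and Gulo. Mup genes encode major urinary proteins and are near-identical copies, so their single values are uncertain. Gulo, an enzyme of vitamin C synthesis, fell 14.3-fold (13.9 ± 11.4 to 0.963 ± 0.199 CPM, SD, n = 5 each, edgeR adjusted p = 0.002). With the hepatocyte covariate these hepatocyte genes stayed called with smaller log2 fold changes. Among them, Mup17 was at -4.75 (-6.61 without it), Cyp2c37 at -3.07 (-4.91) and Gulo at -2.42 (-3.84). Without control 4 the falls were 40.1-fold for Mup9 (61.8 with it), 18-fold for Cyp2c37 (30), 13.4-fold for Cyp2a5 (24.5) and 13.3-fold for Cyp1a2 (20.1). With limma-voom the calls of Mup9 (adjusted p = 0.14), Cyp2c37 (0.061), Cyp2a5 (0.06), Cyp1a2 (0.063) and Mup16 (0.079) ended, the highest adjusted p for each over 24 alternatives, with the lowest at 7.6e-08 for Mup9 and 1.8e-10 for Cyp2c37.

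In all, 2959 of 15043 tested genes changed (19.7%; 1593 rose and 1366 fell), and 733 changed at least 2 times (430 rose and 303 fell). The groups did not overlap for 2323 genes, 15.4% of those tested against 0.79% by chance. The share of calls that rose was 53.8%, against 65.8% with library size alone (1968 rose and 1024 fell) and 73.3% and 73% with limma on log2 TPM. The count fell to 1817 with a hepatocyte covariate and to 1940 without controls 4 and 5, and 374 genes passed the 2-fold threshold with limma on log2(TPM + 1). Of the 33 lists 17 passed, 10 higher and 7 lower, and 5 of them passed with an estimated correlation: central vein, LSEC identity, continuous endothelium, tip cell and vessel matrix.

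**Figure D4:**
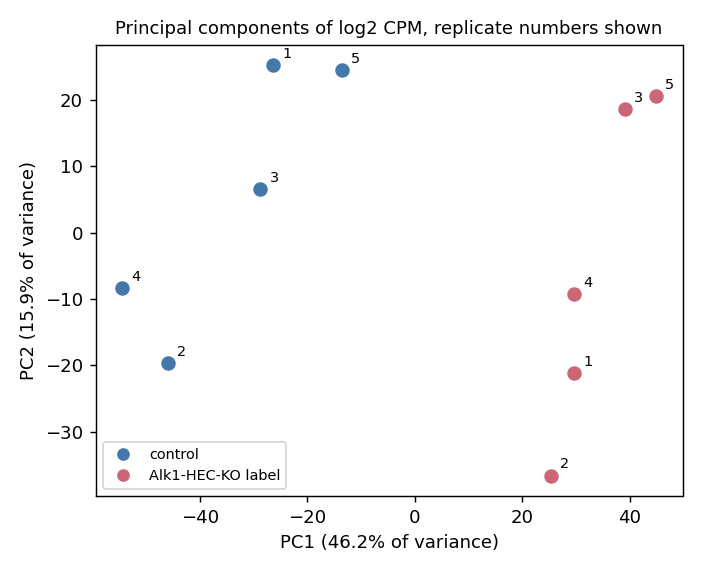
Principal components of log2 CPM over the tested genes, with PC1 (x axis, 46.2% of the variance) and PC2 (y axis, 15.9%) in arbitrary units and 1 point per library, labelled by replicate number. Controls lie between -54.4 and -13.6 on PC1 and knockout-labelled libraries between 25.3 and 44.9, with control 5 the control nearest to them.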

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

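The genes for the tests on control 5 were chosen after its values were seen. Of 290 sets of 5 values (141 named genes and 4 measures per library, in both groups), 17 had a library far from the other 4, where chance gives about 1 in 20, or 14.5.

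Control 5 held more Prnd (4.74 CPM, others at most 0.135), Col28a1 (2.05, at most 0.126), Col15a1 (8.33, at most 2.06), Vwa1 (4.91, at most 1.53) and Igfbp3 (14.7, at most 5.84) than the other controls, all genes that were far higher in the knockout-labelled libraries. A candidate source is a share of RNA, cells or reads from a knockout-labelled library, which needs 1 share for all such genes. A first set, of genes with a mean count of at most 2 in controls 1 to 4 and at least 200 in knockout-labelled libraries, left 2 usable genes, 1 of which fell short of the share, so that set went against it; the gene, Rps12l1, chosen after its values were seen, had reads in knockout-labelled library 5 alone, and the set was changed for that reason. In a set of 18 tested genes, picked next with a laxer limit on controls and a higher minimum (at least 300 counts in knockout-labelled libraries, controls 1 to 4 at no more than 5% of that), control 5 had a pooled excess of 4.98% of the knockout-labelled level, from 1.54 to 6.64% per gene, and 11.1% of the genes fell short of the share by more than 2 times (14.3% of 21 genes with the first minimum of 200, Lrrc55, chosen after its values were seen, among them), which goes with a share but rests on a set changed after its first outcome was known. Cells of such a state within that control would look the same, and no biological explanation was tested.

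Control 4 stood apart with the highest mitochondrial share (6.43%, others 4.27 to 4.74%), the highest share of counts in its top 10 genes (9.23%, others 7.81 to 8.1%), more mt-Nd2 (3990 CPM, others at most 2650) and Flt1 (844, at most 805), and less Sema3g (0.99, at least 3.13) and Col5a1 (3.28, at least 4.49). Control 2 had less Dll4 (212 CPM, others at least 279) and more Gja4 (700, at most 284), and control 3 had more Irf7 (112, at most 85.6). Knockout-labelled library 5 had less Ifit1 (37.7 CPM, others at least 47.7) and Clec9a (34.7, at least 40.6), and library 4 less Sox9 (4.54, at least 7.57).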

How the results depend on the processing

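The fit without controls 4 and 5 was chosen after the data were examined. Acvrl1 stayed higher in the knockout-labelled libraries in all 24 alternatives (log2 fold change 0.84 to 1.01, adjusted p from 3.7e-61 to 5.5e-05). Changed genes numbered 1817 with a hepatocyte covariate (the cause was not tested) and 1940 without controls 4 and 5, where fewer samples were fitted. Genes changed at least 2 times numbered 374 with limma on log2(TPM + 1), where the pseudocount shrinks low genes. With each library left out in turn, counts ran from 2315 to 2870 changed genes, 637 to 838 genes changed at least 2 times and 16 to 20 lists, and Acvrl1 from 0.93 to 0.99. Reversed values were Alb (0.63) and the hepatocyte list (adjusted p = 0.66), both under the hepatocyte covariate, which is made from that list.

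Of the 17 lists 5 passed with a correlation estimated per list, which allows for genes that vary together. The calls it ended had adjusted p of 0.24 (pan-endothelial), 0.23 (arterial and portal, and Wnt feedback), 0.15 (ALK1-BMP targets and interferon), 0.18 (Notch), 0.51 (cholesterol and mitochondrial mRNAs), 0.65 (hepatocytes), 0.47 (B and plasma cells), 0.22 (cholangiocytes) and 0.27 (stellate cells and fibroblasts). For the other list calls that moved, the cause was not tested. Wnt feedback was not called with limma-voom (adjusted p = 0.13), length offsets (0.057), limma on log2 TPM (0.058 and 0.072 with pseudocounts of 1 and 0.1) or rank-based camera (0.25). ALK1-BMP targets were not called with rank-based camera (0.083), hepatocytes with fry (0.17) or cholesterol synthesis without controls 4 and 5 (0.14). Calls were gained for cell cycle with limma-voom (0.014), no filter (0.0088), limma on log2 TPM (0.034 and 0.04), rank-based camera (0.001) and without controls 4 and 5 (0.011). Smooth muscle gained one with limma-voom and length offsets (0.03 each), no filter (0.0039), the stricter filter (0.045), rank-based camera (0.042) and fry (0.03). Dendritic cells gained one with limma-voom (0.045), no filter (0.017), limma on log2(TPM + 0.1) (0.047), rank-based camera (0.021) and fry (0.02). Lymphatic genes gained one with no filter (0.01), rank-based camera (0.03) and fry (0.025), dissociation genes with rank-based camera (0.017), and shear-responsive (0.0062) and mesenchymal transition genes (0.025) with fry, which does not compare a list with other genes. DESeq2 and the fit without robust estimation were not run for lists.

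With 1 library left out in turn, 7 lists crossed the threshold, with adjusted p from 0.0095 to 0.33 for cell cycle, 0.0043 to 0.079 for cholesterol synthesis, 0.047 to 0.17 for dendritic cells, 0.0042 to 0.48 for dissociation genes, 0.023 to 0.17 for lymphatic genes, 0.015 to 0.13 for smooth muscle and 0.0046 to 0.077 for Wnt feedback.

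With the replicate block 2567 genes changed, 721 at least 2 times, 19 lists passed with cell cycle (adjusted p = 0.0064) and smooth muscle (0.045) among them, Acvrl1 was at 0.97, and Mki67 was called (0.53, adjusted p = 0.0023). Deviations of same-numbered libraries correlated at -0.29, 0.55, 0.12, 0.27 and 0.42, and 1 of 5 controls correlated best with its own number. The numbers were therefore not taken to pair the samples. With 5 numbers, most of them with a positive correlation, these values cannot exclude a pairing. The Mki67 and cell cycle results thus depend on that choice.

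Over the named genes, 69 values lost their call with 1 library left out and 1341 did not move across the threshold. In other settings 99 lost it, 6 gained it and 1865 did not move across it. The losses in other settings fell on 35 genes, with adjusted p from 0.05 to 0.31. Beside those named in the report with the setting that ended their call, they were Prox1, Tmem100, Bmpr2, Bmp2, Maf, Vegfc, Klf4, Ccnd1, Mcm3, Aldoa and Col5a1. The others were Zeb2, Irf7, Btg2, Apoa2, Rgs5, Trac, Cd3d, Cd4, Jchain, Mzb1 and, with some of their settings in the report, mt-Nd2, mt-Nd4, mt-Nd6 and mt-Cytb. These calls ended most often with the hepatocyte covariate, no filter or without controls 4 and 5. Fold changes of called named genes moved by over 1.5 times for 29 genes with limma on log2(TPM + 1), where the pseudocount shrinks low genes such as Stmn2 (0.77) and Ebf1 (0.87), for 13 with the hepatocyte covariate, 7 without controls 4 and 5, 6 with limma on log2(TPM + 0.1) and 3 with limma-voom. Beside Esm1 (in DESeq2 and without robust estimation) and Mki67, gains were for Lyve1 with the hepatocyte covariate (adjusted p = 0.023) and Marco (0.0039) and C1qb (0.022) with the macrophage covariate. Of the 2959 called genes, 57.7% (hepatocyte covariate) to 99.6% (DESeq2 size factors) were called in the same direction, and 0 in the opposite one in any setting. The median per-gene shift of the log2 fold change from the main fit was 0.048 with library size alone and -0.003 with DESeq2 size factors. With limma on log2 TPM it was 0.094 and 0.098 for pseudocounts of 1 and 0.1. Simulated 1.5-fold changes were recovered for 68.7% of genes with a control mean of at least 1 CPM, so a gene that did not pass may still differ by that much. Recovery for genes below that level was not simulated.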

Other observations

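All tests here except the splits of the samples were chosen after the results they bear on were seen. Hepatocyte transcripts were lower by zone of the liver lobule. In a list of pericentral hepatocyte genes, written after some of them (Cyp1a2, Cyp2c37 and Cyp2e1 among others) had been seen to fall, 16 of 20 measured members fell and 1 rose (median log2 fold change -3.24). Of the 13 members that were neither named in the report nor in its hepatocyte list 9 fell (median -2.34). Of 17 periportal genes 1 fell and none rose (edgeR; median 0.56; exact permutation p of the list mean 0.34), and of 12 genes of both zones 3 fell and none rose (median -1.18; exact permutation p 0.095). Lect2, Cyp2c50 and Slco1b2, chosen after their values were seen, fell by 4.6 ± 0.72, by 3.39 ± 0.65 and by 3.26 ± 0.63 on the log2 scale (SE), while Glul, which encodes glutamine synthetase and need not come from hepatocytes here (544 CPM in controls, against 471 for Alb), rose by 0.39 ± 0.11 and Apof, listed as periportal, fell by 1.49 ± 0.38.

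A lower share of hepatocyte RNA as the whole cause would lower both zones alike, if the reads of both zones came from hepatocytes. The pericentral minus periportal mean changed by -2.77 (log2, exact two-sided permutation p = 0.0079). Without the genes already named or in the hepatocyte list it changed by -2.21 (exact p = 0.0079). Whether the periportal reads came from hepatocytes was not tested, and the contrast rests on it. Among controls the periportal mean did not follow that of genes of both zones. Control 4 had 2.79 and 6.84 log2 CPM, and control 1 had 3.21 and 5.47. The contrast was 0.1, 0.32 and 0.2 in controls 1, 3 and 5. It was 1.35 and 2.55 in controls 2 and 4, which were highest for both zones. It thus does not cancel hepatocyte load, which may hold part of the change. Knockout-labelled libraries, at 4.42 to 5.6 for both zones, had contrasts of -2.68 to -1.08. Reads that moved between paralogs would leave the summed CPM of a family in place. The sums of Cyp2a, Cyp2c and Cyp3a genes instead changed by -2.83, -2.64 and -2.71 (log2, exact permutation p = 0.0079 each). Those of Cyp1a (-0.77, exact permutation p = 0.071) and Gstm (-0.32, 0.0079) leave it open for these families. The mean Cyp1a sum went from 39.8 to 22.3 CPM, and Cyp1a2 within it from 21.3 to 1.05 CPM. The Gstm sum, 364 CPM in controls, cannot inform on Gstm3, at 2.01 CPM there. The 5 single-copy pericentral genes outside the report and its hepatocyte list (median -1.05, 3 fell) do not settle it. Control 4 alone was not the source, since the difference was -2.36 without it (exact permutation p = 0.0079). What stays open is which hepatocytes or hepatocyte RNA passed the CD146 capture in each group, and a change in the hepatocytes themselves, which was not tested.

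Acvrl1 was higher in the knockout-labelled libraries. Swapped labels would put the ALK1-BMP target list higher there, but its mean there was lower, with a difference of -0.24 (log2 CPM, 12 genes, exact two-sided permutation p = 0.0079), though members went both ways (7 fell, 2 rose) and the list call ended with an estimated correlation (adjusted p = 0.15) and with rank-based camera (0.083). Scaling or depth would bring the log2 fold change near 0 in some alternative, and the lowest was 0.84, with transcript length offsets. A changed mixture of Acvrl1 transcripts may contribute. The mean effective length of Acvrl1, read from the ratio of estimated count to TPM, was 8.8% longer (exact two-sided permutation p = 0.0079). Of 7098 genes 3.1% reached such a shift. With transcript length offsets the log2 fold change was 0.84, against 0.96 in the main fit. The offsets thus left most of the rise in place. They rest on annotated transcripts, so they set no bound on reads from a transcript of the deleted allele that is not annotated. Which exons carry the reads cannot be read from gene-level values, and a biological rise of transcript from the targeted allele was not tested.

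Chance was an unlikely source of the counts of genes, and could not be excluded for the count of lists. Of 100 splits of the 10 libraries into 5 and 5, 1, the real one, gave 2959 changed genes or more, and the highest of the others was 0. For genes changed at least 2 times it was also 1, with 733 against 0. The other splits hold the real difference as spread within their sides, so 0 does not measure how many calls chance alone would give. For the 17 lists that passed, 14 of 100 splits gave as many, with up to 22 in another split. The other 13 were all among the 22 drawn splits that keep 4 libraries of a group together, and so part of the real difference. The 77 that mix the groups as 3 and 2 hold less of it, yet they gave 4 to 16 lists, though no gene was called in them. Camera with the preset correlation thus passed lists even in mixed splits, so its p-values for single lists are less firm than they read. With an estimated correlation 1 of 100 splits gave 5 lists, the real one, and the highest other gave 1.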
